A study of Mus musculus with 2 samples.

How the data were processed

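Binding of EP300 (also called p300), a histone acetyltransferase that acts as a transcriptional coactivator at enhancers and promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in heart tissue of newborn mice (postnatal day 0) of the strain labelled B6NCrl. Both samples belong to 1 group and are labelled replicates 1 and 2. The labels call them biological replicates but give both the same biosample and the same donor identifier, so their agreement measures the spread between these 2 libraries, which may be technical. No other tissue, age or treatment was part of the design, so no groups were compared.

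The authors deposited 5 peak lists on the mm10 assembly (GRCm38). Per the file headers, peaks were called on replicate 1 with 2 control alignment files, on replicate 2 with 1 control file, and on the pooled reads of both replicates with 2 control files. The optimal and the conservative list were then taken by the irreproducible discovery rate (IDR), which keeps peaks that rank alike in 2 lists. Every interval of both stands in the pooled list. Which 2 lists were compared for each is not stated here. The optimal list holds 25 mitochondrial peaks where the replicate 1 list holds 0. A place in the optimal list therefore does not mean that both replicates held the peak. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. Each peak carries the authors' signal value, a height above the control whose exact formula is not stated, the deposited −log10 q of the peak caller, and in the IDR lists the authors' score, a scaled IDR of at most 1000. Signal values were used only to rank and describe peaks within a list. No read counts stand in the files, so the depth is unknown, and no interval that needs it was computed. Intervals given below are 95% exact (Clopper-Pearson) intervals of shares of peaks and cover counting error only.

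Peaks were placed on the GRCm38 sequence and the GENCODE M21 annotation, after checking that every peak and gene lay inside its chromosome. Peaks on the mitochondrial genome and on unplaced contigs were left out of the comparisons, which leaves 17339 of the 17372 peaks of the optimal list. A peak was called promoter-proximal when its summit lay within 1 kb of 1 of 54361 transcription start sites (TSSs) of protein-coding transcripts, and distal otherwise. Each peak within 100 kb of a TSS was assigned to the nearest protein-coding gene, which is a rule of distance and not a measured link. Calls closer than their width are common in these lists, so the counts of peaks per gene hold neighbouring calls. Merged sites join summits within 496 bp.

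The replicates were compared by the share of the 17372 peaks of highest signal in replicate 1 with a summit of the same number of leading peaks of replicate 2 within 100 bp, against 100 random placements on the same chromosomes. The promoter share was set against 100 random placements (two-sided permutation p), and the highest and lowest quintile of peaks by signal were compared by Fisher's exact test. For 17 gene lists (417 entries, all matched to the annotation) the number of assigned peaks was divided by the mean of 10000 random lists of as many protein-coding genes, matched by decile of territory, that is the bases nearest to each gene's TSS, among 21839 genes (two-sided permutation p, Benjamini-Hochberg over the 17 lists). For 27 consensus motifs the share of 200 bp windows at distal summits with a match on either strand was divided by that in windows 1 kb up and downstream of the same summits. An exact sign test on discordant pairs of summit and downstream windows gave p, with Benjamini-Hochberg adjustment over the 27 motifs. The threshold was an adjusted p of 0.05. Peaks with summits within 10 kb were joined into clusters and ranked by summed signal. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

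The groups, tests, gene lists, motifs, the rule for named genes and all alternatives except merged sites were chosen before the data were examined. Named are the nearest gene of the 10 peaks of highest signal, the 10 genes with most peaks, the 3 members with most peaks in each list past the threshold, 12 cardiac genes whatever their values (Nppa, Nppb, Myh6, Myh7, Gata4, Nkx2-5, Tbx5, Mef2c, Hand2, Tnnt2, Ryr2 and Pln), and the nearest gene of the 5 clusters with the highest summed signal. Any other gene named was chosen after its values were seen. The alternatives were other distances for shared summits, promoters and gene assignment, other numbers of leading peaks, the conservative list, above-median peaks, other TSS sets, promoter peaks left out, clusters or members counted once, other motif windows and backgrounds, promoter-proximal motifs, each replicate alone, and merged sites. The list and motif tests were tested on simulated data. With peaks planted on the 21839 genes, 1 of 20 lists raised 1.5-fold, 11 of 20 raised 2-fold and 18 of 20 raised 3-fold passed the threshold, and 0 of 20 unchanged lists did. All 13 planted motifs and 0 of 14 others were called. Each was planted in a larger share of windows than most consensuses reach at the real summits. Those windows lay at random positions, so recovery of rare sites and bias from base composition were not tested. The simulated peaks also stood at random, without the clusters of the real ones. A few genes are not reported here.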

Results

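EP300 binding was mapped in the hearts of newborn mice, at the day of birth, in 2 ChIP-seq replicates. EP300 acetylates histones and is recruited by transcription factors to enhancers and promoters, and its peaks are widely used to find regulatory DNA. The lists of each replicate and of the pooled reads hold 300000 peaks each, and the optimal IDR list, on which the results below rest, holds 17372. Nearly all calls have 1 fixed width, 480 bp in replicate 1, 490 bp in replicate 2 and 496 bp in the pooled and IDR lists. At a deposited −log10 q of at least 2, replicate 1 held 11112 peaks, replicate 2 held 3385 and the optimal list 10019. The conservative list holds 15628 peaks, of which 81.8% overlap an optimal peak, and 73.9% of the optimal peaks overlap a conservative one. Joining summits within 496 bp leaves 14070 sites in the optimal list.

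The first comparison asks how far the replicates found the same sites. The strongest sites recurred in both libraries: the intron of Zbtb16, which encodes a zinc-finger transcription factor, held rank 1 in replicate 1 and rank 4 in replicate 2, and the intron of Per1, a repressor of the circadian clock, held ranks 3 and 1. Among the first 1000 peaks of replicate 1, 93.6% had a summit within 100 bp among the first 17372 peaks of replicate 2, and for the first 1000 of replicate 2 the share was 94.8%. The share fell with rank, to 67.8% for ranks 1001 to 5000 of replicate 1, 41.0% for ranks 5001 to 10000 and 23.3% beyond. Over all 17360 leading peaks of replicate 1 on the main chromosomes, 7412 were shared, or 42.7% (95% interval 42.0% to 43.4%), against 0.145% ± 0.0300 (SD) in 100 random placements. The signal values of the 7412 shared peaks had a Spearman rho of 0.564 and a Pearson r of 0.759, a correlation across peaks, which are not independent replicates. Shared summits lay a median of 29.0 bp apart. Of the 17339 optimal peaks on the main chromosomes, 15076 had a summit of both full replicate lists within 248 bp. This count is no independent measure of agreement, because the optimal list was itself selected from the reads of these replicates. The full lists also hold 300000 calls each, and no random share was computed for it. The shared percentage depends on the distance allowed and on how many peaks are taken, and rose to 58.5% when any overlap of intervals counted.

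**Figure D1:**
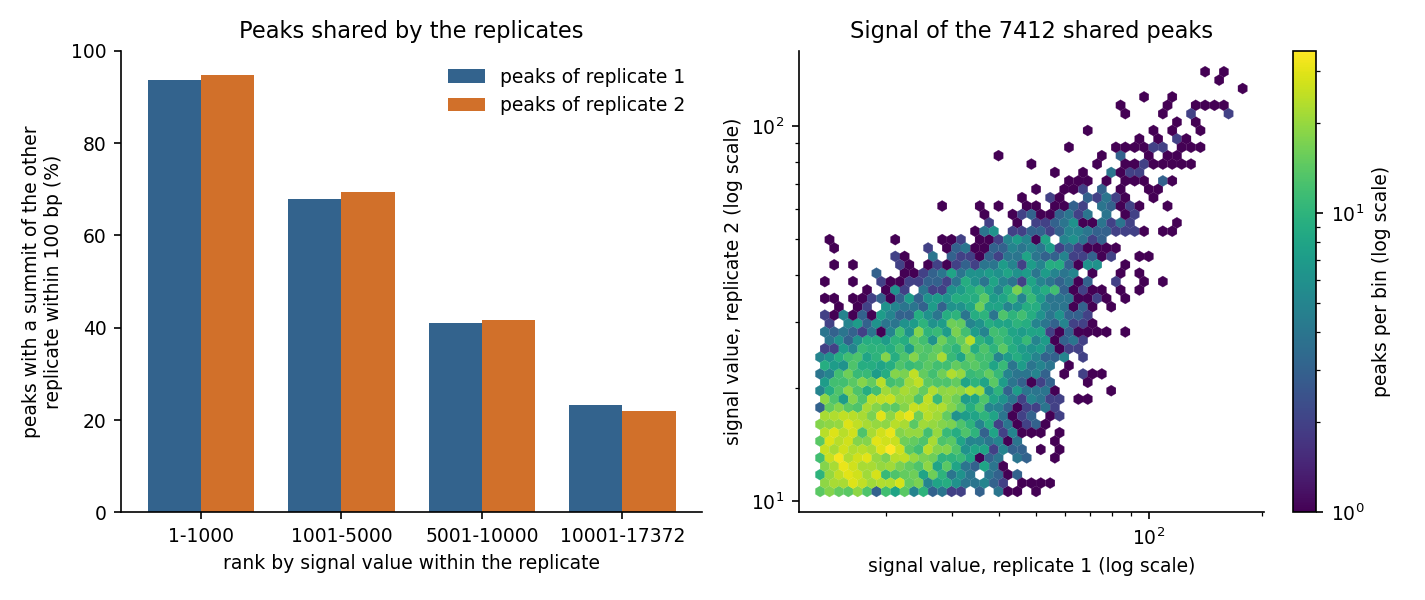
Left, share of peaks (%) of replicate 1 and of replicate 2 with a summit of the other replicate's leading 17372 peaks within 100 bp, by rank of signal; the bars fall from 93.6% and 94.8% in the first 1000 peaks to 23.3% and 21.9% beyond rank 10000. Right, signal value of the 7412 shared peaks in replicate 1 and replicate 2, both axes on a log scale, with the colour giving the number of peaks per bin (log scale).

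The strongest EP300 peaks lay in introns of Zbtb16, Per1 and Klf13 and at the promoters of Cdk12 and Denr. The peak of highest signal, 310.9, lay in an intron of Zbtb16 (chromosome 9, 48723511 to 48723979, mm10), 112170 bp from the gene's TSS, and an intronic peak of 250.1 in the same gene (48740104 to 48740463) ranked the tenth. An intron of Per1 held a peak of 299.8 (chromosome 11, 69096864 to 69097241). The third peak, of 288.3, lay in an intron of Klf13, a Krüppel-like transcription factor (chromosome 7, 63896870 to 63897232), although the nearest annotated TSS is that of E030018B13Rik. Promoters were represented by Cdk12, a kinase of the RNA polymerase II tail, with 281.7 (chromosome 11, 98202538 to 98202883), and by Denr, a translation re-initiation factor, with 266.5 (chromosome 5, 123907074 to 123907364).

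The remaining peaks among the 10 strongest were distal. A peak of 281.5 lay in introns of Gas7 and Glp2r (chromosome 11, 67667680 to 67668000), 27477 bp from the TSS of Rcvrn, and a peak of 280.5 lay in an intron of Timp3, an inhibitor of matrix metalloproteinases, and of Syn3, within which Timp3 lies (chromosome 10, 86341562 to 86341927). Intergenic peaks of 265.6 on chromosome 16 and of 262.1 on chromosome 8 lay 227431 bp from the TSS of Tprg and 142708 bp from that of Irf2bp2. Both are beyond the 100 kb limit, so neither was assigned to a gene.

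Peaks stood in clusters at the most heavily bound genes. The cluster with the highest summed signal, 1013, spanned 16953 bp inside Zbtb16 and held 9 peaks. It was followed by Myh6 (927.4, 29 peaks), which encodes the alpha myosin heavy chain, Tnnt2 (821.0, 21 peaks), which encodes cardiac troponin T, Tns1 (771.7, 15 peaks), which encodes a tensin of focal adhesions, and Txnip (734.6, 16 peaks), which encodes an inhibitor of thioredoxin. Each cluster is named by the gene nearest to its strongest summit, and other peaks in it can lie nearest to other genes. Txnip itself was assigned 9 peaks, with a summed signal of 416.8. In all, the 17339 peaks formed 10550 clusters, of which 6598 were single peaks and 299 held 5 or more. The number of clusters of 5 or more depended on the joining distance, with 151 at 5 kb and 566 at 20 kb. The Zbtb16, Myh6 and Tnnt2 clusters led the list at 5 kb too, while at 20 kb Tns1 came first, and in the conservative list Myh6 came first (summed signal 1431, 43 peaks) and Zbtb16 the second (1006).

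**Figure D2:**
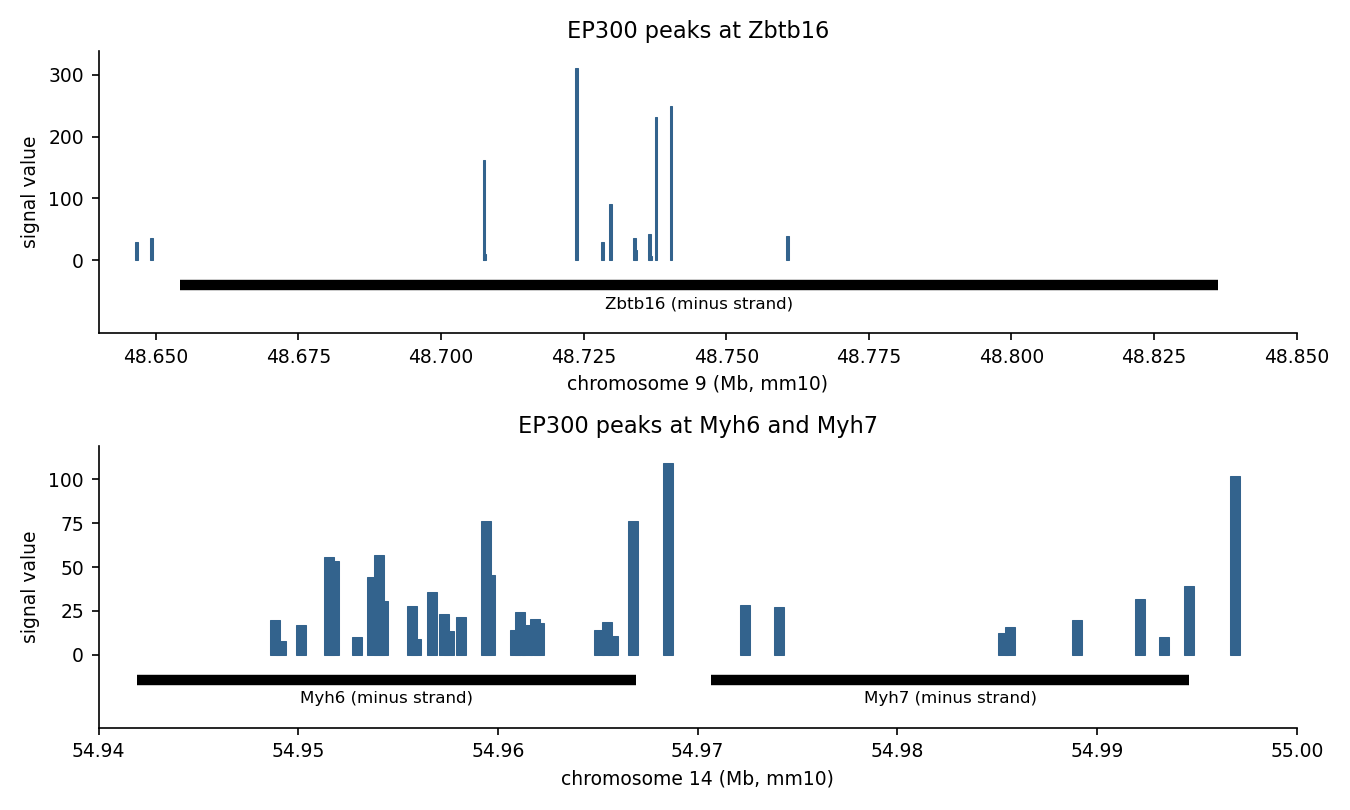
EP300 peaks of the optimal list at Zbtb16 on chromosome 9 (top) and at Myh6 and Myh7 on chromosome 14 (bottom); the horizontal axis is the mm10 position in Mb, each bar spans 1 peak, its height is the authors' signal value, and black bars are genes. The tallest bar at Zbtb16 is the peak of 310.9, and peaks cover much of the body of Myh6, and the tallest in the lower panel is 109.3.

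Among the genes with most assigned peaks were Tns1 and Myh6. Tns1 had 37 peaks in 32 merged sites and Myh6 27 in 14, where a share of peaks proportional to its short territory would be 0.306. Col4a1, a collagen of basement membranes, had 26 peaks, Ablim1, an actin-binding protein, 24, and Rbm20, the splicing factor that acts on titin, 23. Tnnt2 had 21, Mical2, an enzyme that oxidises actin, 20, Irf2bpl 20 and Tcf4, a basic helix-loop-helix factor, 19. Myh6 and Tnnt2, with 14 merged sites each, were the most reduced by merging. These are counts with no test.

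The next comparison asks where in the genome EP300 sat. EP300 peaks were concentrated at promoters: 5810 of 17339 summits, or 33.5% (95% interval 32.8% to 34.2%), lay within 1 kb of a protein-coding TSS, against 2.69% ± 0.134 (SD) at random positions, a ratio of 12.4 (permutation p = 0.0198, the smallest that 100 placements can give). Introns held 32.4% of the summits and intergenic DNA 31.1%, against 36.5% and 57.5% of random positions, and coding exons held 0.756% against 1.23%. A summit near a TSS was counted as promoter only, so the promoter excess lowers the shares of the other classes. These shares therefore do not show that distal peaks avoid introns. Among distal peaks, 5611 summits lay in introns and 5401 in intergenic DNA, while random positions fell more often in intergenic DNA. Relative to intergenic DNA, introns thus held more distal peaks than random positions would give. The ratio to random positions was 0.886 for introns and 0.542 for intergenic DNA. The median distance to the nearest TSS was 8080 bp, and 11529 peaks were distal. After Cdk12 and Denr, the strongest promoter peaks lay at Wdr77 (238.1), Ostc (233.6), Slc25a4, the heart and muscle ADP/ATP carrier (222.7), Riok2 (220.4), Taf6 (216.6), Popdc2, a membrane protein of muscle (214.2), and Tnnt2 (212.8). These were named after their values were seen.

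Whether strong or weak peaks lay more often at promoters depended on the list of peaks. In the highest quintile by signal 33.9% of 3467 peaks were promoter-proximal, and in the lowest quintile 38.6% (odds ratio 0.819, Fisher's exact test, two-sided, p = 7.1e-05). The odds ratio was 1.10 (Fisher's exact test, p = 0.104) after overlapping calls were merged, and it was 1.47 with replicate 2 alone and 1.44 with replicate 1 alone.

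**Figure D3:**
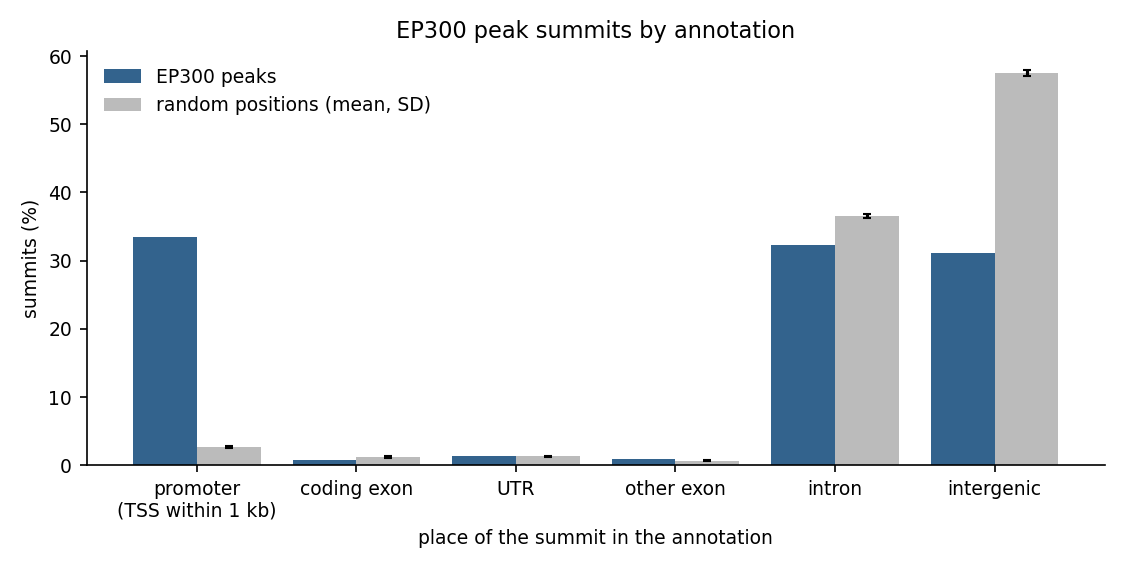
Share of EP300 peak summits (%, blue) and of random positions (%, grey, mean with SD as error bar) in each class of the annotation; promoter means a summit within 1 kb of a protein-coding TSS. Promoters hold 33.5% of the peaks and 2.69% of random positions, and intergenic DNA holds 31.1% and 57.5%.

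The gene lists ask which cell types and programmes of the heart the peaks belonged to. Genes of heart muscle held far more EP300 peaks than matched random genes. The 30 genes of the sarcomere and Z-disc held 173 peaks, 8.12 times the 21.3 ± 8.32 (SD) of random lists, and 26 of the 30 had at least 1. Myh6 (27 peaks), Tnnt2 (21) and Actc1, cardiac actin (12), led this list. Its ratio rests in part on neighbouring calls at such genes: it was 3.08 with clusters counted once and 2.69 for members with a peak, and with clusters counted once the endothelial (3.92), fatty acid oxidation (3.87), hormone (3.82) and transcription factor (3.16) lists lay above it. Hormone and stress-response genes held 73 peaks, 6.11 times the random mean, led by Fhl2, a LIM-domain protein of the Z-disc (11), Nppb, the B-type natriuretic peptide (9), and Myh7, the beta myosin heavy chain (9). Cardiac transcription factors held 116, 4.20 times the random mean, led by Myocd, the coactivator of serum response factor (18), Gata4 (15) and Gata6 (12). The adjusted permutation p of each of these 3 lists was 0.00068, from a raw p of 0.0002, the smallest that 10000 random lists can give.

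Genes of calcium handling, ion channels and gap junctions held 86 peaks, 3.16 times the random mean (adjusted permutation p = 0.0023). Cacnb2, a calcium channel subunit, and Jph2, which ties the cell membrane to the sarcoplasmic reticulum, had 10 peaks each, and Pln, the inhibitor of the calcium pump, had 9. In this list 17 of 24 genes had a peak, while the pacemaker channels Hcn2 and Hcn4, named after their values were seen, had none.

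The 12 cardiac genes fixed in advance differed widely in number of peaks. Besides Myh6, Tnnt2, Gata4, Nppb, Myh7 and Pln, named above, Mef2c had 7 peaks, Ryr2, the calcium release channel, 7, Nkx2-5 6, Hand2 4, and Tbx5 and Nppa 1 each. The strongest peak assigned to Ryr2 reached 207.2 and that of Pln 147.4, and the single peak of Tbx5 reached 26.4. Nppa and Nppb are neighbours on chromosome 4, so peaks between them go to the nearer TSS. With replicate 1 alone Ryr2 had 11 peaks, Tbx5 3, Myh7 15, Nppb 5, Cacnb2 5, Tcf4 12 and Smtn 3, and with replicate 2 alone Ryr2 had 12, Mef2c 4 and Fhl2 5.

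Genes of energy metabolism and of the vascular lining also held more peaks than matched random genes. Those of fatty acid oxidation and mitochondrial energy held 83 peaks, 4.27 times the random mean (adjusted permutation p = 0.00068), with 9 each at Ppargc1a, a coactivator of mitochondrial genes, Cd36, a fatty acid transporter, and Lpl, lipoprotein lipase. Of the 29 genes, 25 had a peak. Endothelial and endocardial genes held 113 peaks, 4.67 times the random mean (adjusted permutation p = 0.00068), and 26 of 28 had a peak. Kdr, the main receptor of vascular endothelial growth factor, had 10, and Egfl7 and Fli1, an ETS factor of endothelium and blood, had 9 each. These 2 lists and the 4 heart muscle lists passed the threshold under all 10 alternatives, but counting members with a peak in place of peaks lowered their ratios, to 2.83 for fatty acid oxidation, 2.68 for endothelium, 2.83 for hormones, 1.99 for transcription factors and 1.78 for calcium handling. By that count ribosomal protein genes, described below, had 2.77, above the sarcomere, endothelial, transcription factor and calcium lists. Random lists were matched by territory and not by expression, so such ratios are not particular to genes of the heart.

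Of the lists for other cell types of the heart, only smooth muscle passed the threshold. Smooth muscle and pericyte genes held 46 peaks, 3.0 times the random mean (adjusted permutation p = 0.0155), but 18 of them belong to Myocd, which is also expressed in heart muscle, 7 to Smtn and 6 to Mylk, the myosin light chain kinase. Counting members with a peak in place of peaks, the ratio was 1.29 and the list did not pass, nor did it among above-median peaks (2.25). Genes of fibroblasts and extracellular matrix held 35 peaks (ratio 1.41, adjusted permutation p = 0.367), those of the epicardium 4 (0.263, p = 0.121), of macrophages and leukocytes 9 (0.594, p = 0.412) and of erythroid cells 8 (0.568, p = 0.412). The macrophage list passed as depleted with replicate 1 alone (0.265) and on the conservative list (0.221), and so did the epicardial list on the conservative list (0.145). Haemoglobin genes, named after their values were seen, held none.

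Genes that respond to the YAP and TEAD factors of the Hippo pathway held 48 peaks, 2.48 times the random mean (adjusted permutation p = 0.0229), with 7 each at Ankrd1, a stress-response protein of heart muscle, and Gadd45b, and 6 at Amotl2, which binds YAP. The call was lost in 3 alternatives, among them promoter peaks left out (ratio 2.35). Ribosomal protein genes held 33 peaks, 2.70 times the random mean (adjusted permutation p = 0.0156), with 3 at Rpl3 and 2 at Rpl10a. Without promoter peaks the ratio of the ribosomal list was 1.10 and it did not pass. Cell cycle genes held 27 (2.14, adjusted permutation p = 0.0691) and passed in 7 of 10 alternatives, among them each replicate alone (2.48 and 2.5).

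Neuronal and liver genes, taken as contrast tissues, held few peaks. Neuronal genes held 7 peaks, 0.251 times the random mean (adjusted permutation p = 0.0155), 2 each at Rbfox3, Syt4 and Dlx2. Liver genes held 4, 0.185 times the random mean (adjusted permutation p = 0.0092), 2 at Ambp and 1 each at G6pc, glucose-6-phosphatase, and Ttr, transthyretin. Both calls of depletion were lost with promoter peaks left out, at ratios of 0.294 and 0.300, and among above-median peaks, at 0.363 and 0.277. Skeletal muscle genes, many of them close relatives of the cardiac ones, held 17 (0.882, adjusted permutation p = 0.893).

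**Figure D4:**
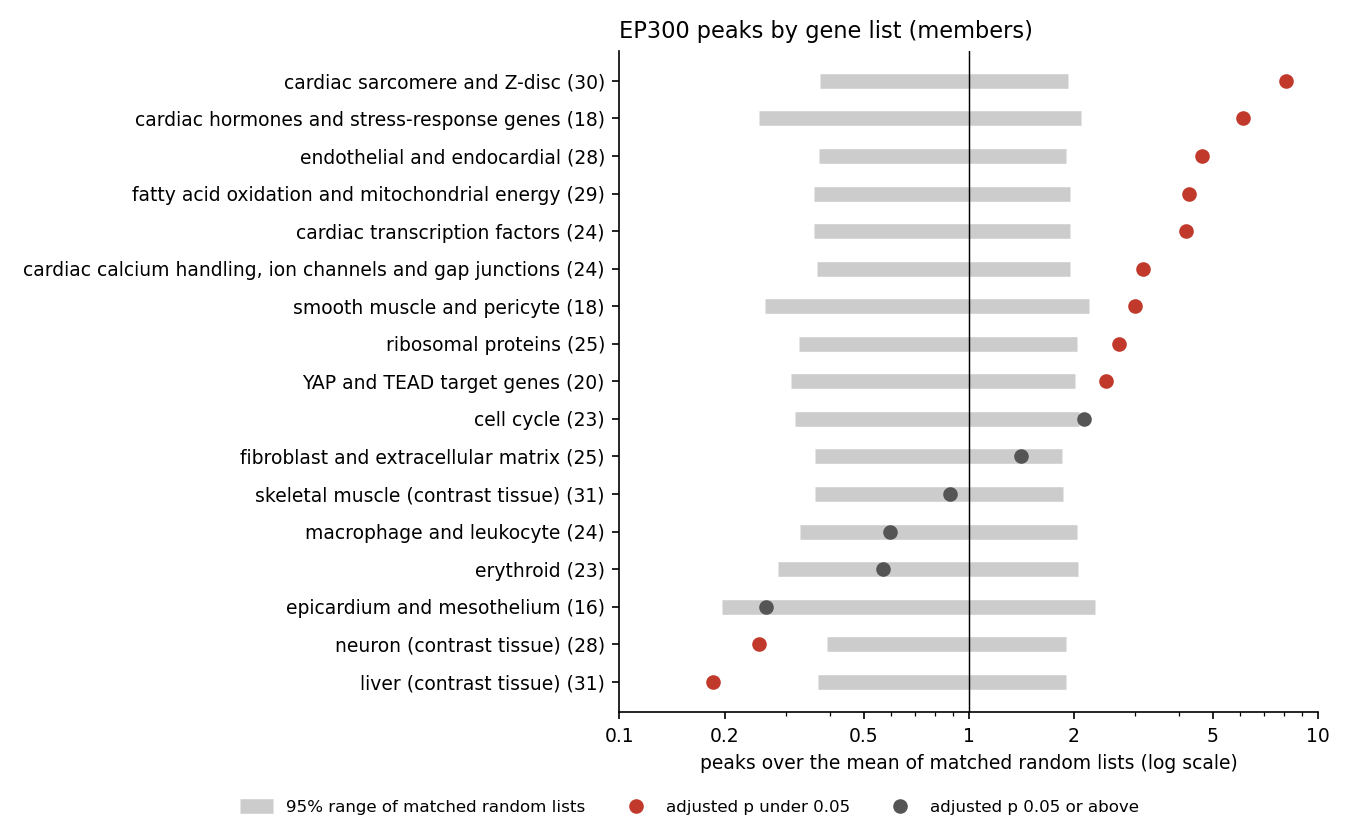
EP300 peaks assigned to each of the 17 gene lists, divided by the mean of matched random lists (log scale), with the number of members in parentheses; grey bars are the 95% range of 10000 random lists, red points have an adjusted p under 0.05 and dark grey points do not. Counted in peaks, the sarcomere list stands highest at 8.12 and the liver list lowest at 0.185.

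The last comparison asks which transcription factor sites lay under the distal peaks. Sites of the known cardiac and endothelial regulators were over-represented at the summits. The class A E-box CAGCTG, bound by basic helix-loop-helix dimers, was in 20.9% of 11529 windows against 10.1% of flanks (ratio 2.06, exact sign test, adjusted p = 2.2e-113). The endothelial and blood type of ETS site was in 11.8% against 4.12% (2.87, exact sign test, adjusted p = 6.5e-108), the TEAD site in 8.98% against 3.40% (2.64, adjusted p = 2.9e-69), the MEF2 site in 7.31% against 2.91% (2.52, adjusted p = 1.8e-53) and the GATA site in 6.28% against 2.33% (2.70, adjusted p = 1.6e-47). The windows are parts of 1 pooled list, so these p-values compare positions and not animals.

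Sites of other heart regulators and of general factors were over-represented too. The ratio was 2.12 for MEIS, 1.89 for the CArG box of serum response factor, 1.83 for AP-1, 1.83 for SOX, 1.51 for HAND, 1.5 for NKX2 and 1.27 for forkhead factors. CTCF, which organises chromatin loops, had a ratio of 5.23 at 0.885% of windows, STAT 2.92, CREB 3.64, the promoter type of ETS site 3.12 and the KLF and SP site 2.37. The PU.1 site, taken as a myeloid contrast, had a ratio of 2.23, and its consensus shares the ETS core. The NFI site was in 11 windows in all and lost its call in 6 of 9 alternatives. The forkhead call was lost among above-median peaks (1.24) and the KLF call with replicate 2 alone (1.72). In all 19 of 27 motifs passed, all of them enriched.

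The T-box site AGGTGTGA was in 0.989% of summit windows and 0.980% of flanks (ratio 1.01, exact sign test, adjusted p = 0.687), although the T-box factors Tbx5 and Tbx20 act in heart muscle. The site of ERR nuclear receptors had a ratio of 1.05, and those of NRF1, RUNX, HNF4, HNF1, RFX and the octamer did not pass either, with ratios of 1.67, 0.864, 1.12, 0, 2.14 and 0.817. Under promoter-proximal peaks 9 motifs were enriched in place of 19, and the ratio of the MEF2 site was 0.615 and that of the GATA site 0.718, below the flanks, while the NRF1 site rose to 4.67 times the flanks and the RFX site, rare in both, was in 0.172% of windows and 0.00861% of flanks. The RUNX, octamer and RFX sites stayed below the threshold in only 4, 6 and 5 of 9 alternatives. In the others the RUNX (0.862 with replicate 1 alone, 0.778 on the conservative list) and octamer sites (0.721 and 0.790) passed as depleted and the RFX site (3.40 and 3.08) as enriched. Against shuffled sequence the NKX2 ratio at distal peaks was 1.03 and did not pass, while the ERR (3.03) and RFX (5) sites passed. The MEF2 ratio at distal peaks was 9.16 with that background, so ratios depend on the base composition of the background. Promoter-proximal peaks were not set against shuffled sequence. Their ratios to the flanks can therefore not be told apart from a difference in base composition.

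**Figure D5:**
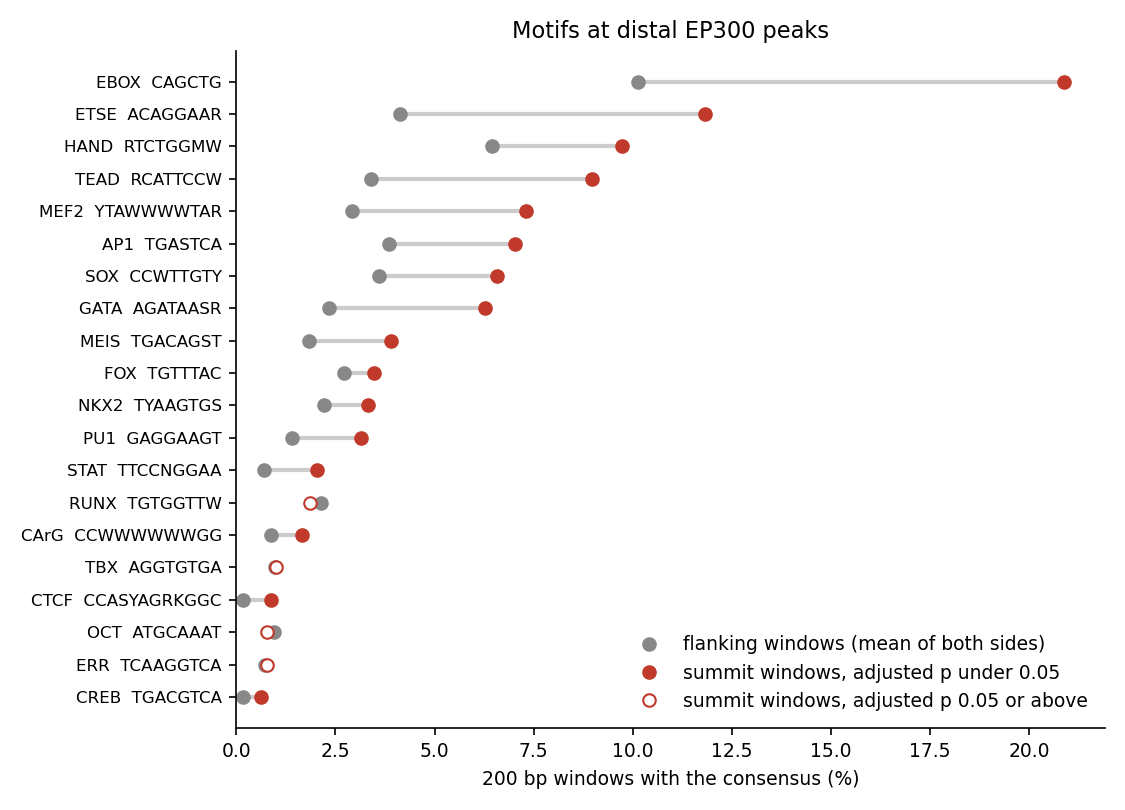
Share (%) of 200 bp windows with each consensus at the summits of distal EP300 peaks (red, filled where the adjusted p is under 0.05) and in the flanking windows (grey), for the motifs found in at least 0.5% of summit windows. The E-box CAGCTG reaches 20.9% against 10.1%, and the points of the T-box site coincide at 0.989% and 0.980%.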

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

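Both tests of the mitochondrial peaks and the test of overlapping calls were chosen only after the result was seen. The labels give no group that differs in these patterns, so no biological explanation was tested for either.

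The optimal list holds 25 peaks on the mitochondrial genome, which none of the comparisons above uses. The replicate 2 list holds 21, the pooled list 25, and the replicate 1 and conservative lists 0, and whether mitochondrial reads were removed from replicate 1 alone was not tested. Replicate 2 was called against 1 control file and replicate 1 against 2, so a control set used for replicate 2 alone was tested as the source. The pooled list was called with the 2 control files of replicate 1 and still holds 25, which argues against it. What stays open is excess coverage of the whole mitochondrial genome: the 25 peaks cover 60.5% of its 16299 bp at a median spacing of 416.0 bp, which may reflect mitochondrial DNA in the library of a tissue rich in mitochondria and not sites of EP300. The optimal list also holds 8 peaks on unplaced contigs, outside the comparisons above.

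A further 3806 peaks of the optimal list, or 22.0% of those on the main chromosomes, rank below 17372 by signal in the pooled list, although the list itself is only that long. Of these, 68.8% overlap a pooled peak of higher signal, against 10.5% of equally ranked pooled peaks outside the list, a ratio of 6.57. Split calls at the edge of a strong peak, kept by overlap with a strong peak of a compared list, are a candidate explanation. In the lowest quintile by signal 73.2% of peaks overlapped a stronger one, and in the highest quintile 1.76%. A signal in 1 library alone stays open for part of them: 42.0% lay near a leading peak of exactly 1 replicate, 20.6% near one of both and 37.4% near one of neither.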

How the results depend on the processing

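The alternative that merges overlapping calls into sites was chosen only after the data were seen; all others were planned. Shared summits of the replicates came to 30.5% within 50 bp, 51.4% within 200 bp, 58.5% by overlap of intervals, 51.5% among the first 5000 peaks and 26.3% among the first 50000, against at most 0.706% at random, and Spearman's rho to 0.525 and 0.579 for the first 5000 and 50000. The promoter share stayed above random in all 9 alternatives, at 28.5% to 39.9%. The promoter odds ratio of strong against weak peaks turned from 0.819 to 1.00 between peaks above and below the median signal, 1.10 with merged sites, and 1.44 to 1.47 with each replicate alone; the cause was not tested. Of gene lists, 7 were enriched among above-median peaks and 7 without promoter peaks, in place of 9, and fewer peaks entered both. Lists below the threshold changed side of 1: fibroblast genes had 0.573 among above-median peaks and 0.963 to 1.34 with each replicate alone, skeletal muscle genes 1.18 with a TSS within 20 kb. Under promoter-proximal peaks, which are other peaks, 9 motifs were enriched and 14 lay below the flanks, 12 of which lay above them under distal peaks: TBX 0.309, NKX2 0.549, MEF2 0.615, ERR 0.704, MEIS 0.710, GATA 0.718, HAND 0.776, SOX 0.824, FOX 0.855, HNF4 0.88, AP-1 0.949 and CArG 0.951. For promoter-proximal peaks no shuffled background was run, so an effect of base composition on these ratios was not tested. Clusters of 5 or more peaks numbered 151 at 5 kb and 566 at 20 kb, by construction. Read depth is unknown, so its limit on weak peaks was not assessed, and 3-fold changes were the size that the simulated lists mostly recovered. No paired analysis was possible because there is 1 group.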

Other observations

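The 4 gene lists and 4 consensuses described here were drawn up only after the strongest peaks had been seen, the genes named here were chosen after their values were seen, and the same holds for the merging of overlapping calls in the comparisons by signal. The 4 tests of the glucocorticoid receptor hypothesis were set before their own results were seen, except that the test of 1 library alone was set anew after the sharing of the strongest peaks was known. The rule that labels the test of repeats was changed after its result was seen: the first rule, a difference between the strongest and the other summits, left that test undecided (Fisher's exact test, p = 0.379), and the later one asks whether most of the strongest summits lie in repeats.

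Clock genes and signalling genes of the developing heart held many EP300 peaks. A list of 21 circadian clock genes held 70 peaks, 4.30 times matched random lists (adjusted permutation p = 0.0004, over 4 lists), and 59 peaks, 3.85 times the random mean (permutation p = 0.0008), without Per1 and Per2. Nr1d1 and Bhlhe40, transcriptional repressors of the clock, had 9 each and Hlf 6, while Clock and Cry1 had none. Nr1d1 was also the nearest gene of a cluster of high summed signal (632.9, 15 peaks). The 19 genes without Per1 and Per2 may thus include genes whose peaks had been seen. The E-box CACGTG, bound by clock factors among others, was in 5.49% of distal summit windows and 3.07% of flanks (ratio 1.79), and in 7.68% of the highest quintile by signal against 3.21% of the lowest (8.36% and 4.52% after overlapping calls were merged). The site of the clock output factors of the Dbp type was in 1.65% of summit windows and 1.43% of flanks (exact sign test, adjusted p = 0.147). It was in 2.00% of the highest quintile and 0.954% of the lowest (Fisher's exact test, adjusted p = 0.0102). After overlapping calls were merged the shares were 1.92% and 1.45% (Fisher's exact test, adjusted p = 0.554). Genes of BMP, TGF-beta and Notch signalling held 72 peaks, 3.06 times the random mean (adjusted permutation p = 0.0024), led by Id1 (10), Smad7 (9), Hes1 (8) and Smad6 (7), which are targets or inhibitors of these pathways. Of the ligands in the list, Bmp10 and Jag1 had 4 each and Tgfb1 2, and Bmp2, Bmp4 and Tgfb3 had none. Subunits of the respiratory chain held 16 peaks over 25 genes (ratio 1.23, adjusted permutation p = 0.583), and the difference from the genes of fatty acid oxidation was not tested.

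Ventricular and atrial myosin light chains differed in number of peaks, a difference that was not tested. Myl2 and Myl3, the ventricular myosin light chains, had 11 and 7 peaks, and Myl7 and Myl4, the atrial ones, had none, while Mylpf, of skeletal muscle, had 2. The contractile genes of smooth muscle Acta2, Myh11, Tagln and Cnn1 also had none. Stronger distal peaks held more GATA sites, 9.89% in the highest quintile by signal against 3.34% in the lowest (Fisher's exact test, adjusted p = 3.7e-18 over 31 motifs), and 10.3% against 5.14% after overlapping calls were merged. The MEF2 site differed between the same quintiles, 8.07% against 4.95% (Fisher's exact test, adjusted p = 7.1e-05), but was in 7.64% to 8.07% of each of the upper 4, and with merged calls the difference did not pass, at 8.0% against 7.58% (Fisher's exact test, adjusted p = 0.804). The X chromosome held 170 peaks of the optimal list, 1.04 per Mb of sequence, where the autosomes held 7.17 and no autosome fewer than 5.18. Per protein-coding gene it held 0.179 peaks and the autosomes 0.829. In the lists of 300000 peaks the autosomes exceeded the X chromosome 2.91-fold in replicate 1 and 2.81-fold in replicate 2, and no list held a peak on the Y chromosome. The labels do not record the sex of the mice.

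Sites resembling those of the glucocorticoid receptor lay under several of the strongest distal peaks. The 15 bp palindrome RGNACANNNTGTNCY was in 1.88% of distal summit windows and 0.186% of flanks (ratio 10.1, exact sign test, adjusted p = 2.3e-40). A variant with 1 strong arm, AGAACANNNTGTNC, had a ratio of 10.5. Of the matches of the palindrome within 200 bp of a summit, 72.7% lay within 50 bp of it. Of the 10 strongest peaks 8 were distal, and 6 of those 8 held a match, as did 17 of the 100 strongest distal peaks. At Zbtb16 the match was AGTACAGAGTGTACC (chromosome 9, 48723703 to 48723717), in the intron of Per1 AGAACACGATGTTCC (chromosome 11, 69097076 to 69097090) and in that of Klf13, nearest to the TSS of E030018B13Rik, GGAACAGCATGTTCT (chromosome 7, 63897089 to 63897103). The other matches among the 10 strongest peaks lay nearest to the TSSs of Rcvrn, Timp3 and Tprg. Matches under weaker peaks lay near Gata6 (signal 220.5), Fkbp5 (167.9), Ddit4 (164.3) and Nppb (96.4), among many others. Rcvrn, Timp3, Tprg, Gata6 and Nppb are not in the list of known targets used below.

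Activity of the glucocorticoid receptor in the newborn heart is a hypothesis for why several of the strongest peaks lie at its known target genes. The consensus was in 4.03% of the highest quintile of distal peaks by signal and 0.738% of the lowest, a ratio of 5.47 (Fisher's exact test, p = 3.8e-14), with 2.04%, 1.52% and 1.08% between them. The ratio fell to 3.08 (4.0% and 1.30%, Fisher's exact test, p = 1.7e-07) when overlapping calls, which fill much of the lowest quintile, were merged. Before merging, sites of other factors rose with signal too, among them GATA (2.96), MEIS (2.59) and CACGTG (2.39). Others did not, among them forkhead (0.926) and RUNX (0.558). With merged calls the CREB site had a ratio of 3.75, in 15 and 4 windows. A list of 30 known targets held 137 peaks (ratio 5.57). The 24 without the genes that gave rise to the idea held 96 peaks, 4.80 times matched random lists (permutation p = 0.0002, the smallest that 10000 lists can give). Among the 24, Fkbp5 had 8, Dusp1 9 and Tgm2 16. Tgm2 was also the nearest gene of a cluster of high summed signal (475.6, 13 peaks). The 24 may thus include genes whose peaks had been seen. Lists chosen with no regard to the receptor had ratios on both sides of 4.80 (sarcomere 8.12, hormones 6.11, endothelial 4.67, fatty acid oxidation 4.27), with no test of the differences. The test of repeats does not decide. Of the 100 strongest distal summits 6.0% (95% exact interval 2.23% to 12.6%) lay in repeat-masked sequence, and 8.86% of the others (Fisher's exact test, p = 0.379). The interval shows only that most of these 100 lay outside repeats, by the rule set after the result was seen. A signal in 1 library alone is argued against for the strongest distal peaks in general, by a test set after their sharing was known. At least 97 of the 100 strongest distal peaks in each replicate's own list were among the first 1000 peaks of the other. Both libraries carry the same biosample label, so their agreement does not speak to a feature of that sample. What stays open is whether any receptor may be bound at all, since only EP300 peaks and a consensus were examined, and which one, because mineralocorticoid, progesterone and androgen receptors share this site and no steroid treatment or level was measured.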
